A study of Mus musculus with 3 samples.

How the data were processed

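Leukocytes from peripheral blood of untreated mice were profiled by droplet single-cell RNA sequencing in 3 libraries. Per the labels, erythrocytes were lysed, cells were sorted after DAPI and Draq5 staining, fixed, and processed with the fixed-RNA kit of 10x Genomics in its multiplexed format on a Chromium X, in which probes against transcripts are counted rather than whole transcripts. The deposited matrices hold raw UMI counts per gene and barcode, with no normalization, for 19059 genes, and the barcode and feature lists deposited beside them hold identifiers only (unit: other, not a measurement). Cell Ranger 7.1.0 made them per the file headers. The genome build and the probe set version are not given in the sources used here. The matrices hold called cells, since the lowest barcode totals were 505, 499 and 504 UMIs. Mx1, Cx3cr1, Ly6c2, Ahsp, Clec7a, Ccnb1 and Stfa2l1 have no entry in the matrices and were not analysed here.

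The labels place the 3 libraries in 1 untreated group and give ages of 8, 9 and 10 weeks, 1 library each, so no age was compared with another. They do not state that the libraries come from separate animals. If they do not, the p-values given here measure the spread between these samples. The 3 libraries differed by more than sampling noise: over genes with at least 20 counts, the chi-square per degree of freedom of each pair was 327, 189 and 82.7.

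Barcodes with fewer than 200 genes were removed. Doublets were called per library with Scrublet in scanpy 1.11.5 and removed, which left 21767 cells. Counts were scaled to 10000 per cell and log-transformed, and 2000 highly variable genes, chosen per library and merged, went into a principal component analysis (30 components), a graph of 15 nearest neighbours and Leiden clustering at resolution 1. Genes of the 11 outcome lists and mitochondrial genes were held out of the clustering. No integration of the libraries was applied. Each cluster was scored against 19 marker lists by the mean log2 ratio of its expression to the mean of the other clusters (pseudocount 0.2). A name needed a score of 0.7, at least 3 markers in 10% or more of the cells, and no list of an unrelated type at a score of 1 or more. A cluster of low depth with no marker of its type among its top 10 genes also stayed unnamed. These thresholds were set after the clusters had been seen. All names end in "like", since they rest on transcripts alone. Monocyte-like cells are the Ly6c-high-like and Ly6c-low-like classes together.

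Fixed before the data were examined were the comparisons, the lists, the alternatives in the first set and the rule for named genes. The outcome lists held 216 genes, of which 213 are in the matrices, and the marker lists held 141, of which 137 are. The outcome lists are splenic macrophage, efferocytosis, LXR and lipid handling, interferon-stimulated, MHC class II presentation, tissue repair, inflammatory, adhesion and trafficking, phagocytic receptor and lysosome, immediate-early and heat shock, and proliferation. The named genes are always Siglec1, Timd4 and Nr1h3. For each comparison and list they are also the 2 members with the highest and the 2 with the lowest log2 fold among those past the threshold, moved the same way in all 3 samples and at 10 CPM or more in an arm. To these come the 8 highest and the 8 lowest genes per comparison at 20 CPM or more that are in no marker list and were not used for clustering. Any other gene named was chosen after its values were seen.

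Raw counts were summed per sample and class. Sums were tested with edgeR 4.0.16 (quasi-likelihood, robust, filterByExpr, TMM), with the sample as a block, at a Benjamini-Hochberg adjusted p of 0.05. The block pairs classes of the same library by design. The comparison of monocyte-like with neutrophil-like cells and with the mean of the other classes used 1 fit of the 8 classes with at least 20 cells in every sample. The comparison of Ly6c-low-like with Ly6c-high-like cells used those 2 classes alone. For the comparison by Siglec1, each monocyte-like cell with at least 1 Siglec1 UMI was matched to up to 3 cells without one from the same sample and cluster with the nearest UMI total, and Siglec1 was left out of the test. Siglec1 and the outcome lists had no part in the clustering, but the classes come from the same cells, so counts of genes not used for clustering are given beside the totals. SE values are those implied by the log2 fold and its F statistic. Levels are TMM-scaled CPM, that is CPM divided by the TMM factor, as mean ± SD over 3 samples, and plain CPM where so named. A value of a fold against a group with no UMI is a lower bound against 3 counts over the group, and a group with 1 to 3 UMIs has an exact 95% interval of the pooled ratio. Pooled Siglec1 ratios and bounds use library totals times their TMM factors, and plain totals for erythroid-like and basophil-like cells, which are outside the shared fit.

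Lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01, and again with the correlation estimated per list. They were also tested with fry of limma. Of the calls made at the preset correlation in the 3 comparisons, none held an adjusted p under 0.05 with the estimated one. Tests of genes were checked on simulated counts with 200 changed genes on the same library sizes. The simulated spread was assumed rather than estimated from these data, and its replicate effect was shared by both arms. The shares recovered hold for that spread and can differ where a change varies between replicates. At a simulated 2-fold change, 92.3% of genes were recovered between monocyte-like and neutrophil-like cells, 78.1% between the monocyte classes and 69.4% between the Siglec1 arms. At 1.5-fold these shares were 39.4%, 21.2% and 18.2%, and at 4-fold they were 100% in each. False calls made up 6.83%, 2.27% and 0.84% of the calls in the same order. For the neutrophil comparison both this check and the regrouping of samples used a fit of the 2 compared classes.

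Alternatives were DESeq2 size factors within edgeR, a DESeq2 1.42.0 Wald test, no filter beyond 1 count, no sample block, doublets kept, each replicate left out, Leiden resolutions of 0.5 and 2, a minimum of 500 genes per cell, a fit of the compared classes alone, unmatched Siglec1 arms and a minimum of 2 Siglec1 UMIs. Plain library totals without a scaling factor, removal of cells with 2 or more UMIs of 18 lymphocyte markers, and a restriction to Ly6c-high-like cells were added after seeing the data. Shares of cells have exact Clopper-Pearson 95% intervals, which cover counting error only. To compare shares at equal depth, cells were thinned to 2000 UMIs and shallower cells were left out. Gene positions are from GENCODE release M21 on GRCm38, matched by Ensembl identifier. Timd4 had too few UMIs for its planned tests. Of the genes named by the rule or found in the lists, 2 are not reported here by name, and the counts of the lists include them.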

Results

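The data are UMI counts from 3 libraries of untreated mouse blood leukocytes, here called replicates 1, 2 and 3. Replicate 1 held 45718031 UMIs in 11105 barcodes, replicate 2 held 19591648 in 5736 and replicate 3 held 23443660 in 7029. The median barcode had 3539, 3138 and 3086 UMIs. After filtering, 10337, 4935 and 6495 cells were analysed, with medians of 3474, 3273 and 3130 UMIs. The title of the study concerns splenic macrophages that carry CD169, the sialic acid receptor encoded by Siglec1, and Tim4, the phosphatidylserine receptor encoded by Timd4. In these blood samples, the comparisons ask which circulating cells carry the transcripts of Siglec1 and Timd4, how the circulating phagocytes differ in macrophage, efferocytosis, lipid, interferon, presentation and repair genes, and which genes go with Siglec1.

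B-lineage-like cells were the largest class, with 46.0% ± 16.7 of cells (SD, n = 3) and a range of 28.3% to 61.5%. CD8 T-like cells made up 13.4% ± 5.39, CD4 T-like cells 12.5% ± 5.31, neutrophil-like cells 11.5% ± 4.70 and NK-like cells 3.61% ± 2.53. Ly6c-high-like monocytes, whose class was led by Chil3, F13a1, Fn1 and Ccr2, made up 2.97% ± 1.00. Ly6c-low-like monocytes, led by Ace, Nr4a1, Treml4 and Cd300e, made up 2.58% ± 1.69. Platelet-like cells made up 1.69% ± 1.11, erythroid-like cells 1.11% ± 1.32, dendritic-like cells 0.493% ± 0.133 and basophil-like cells 0.310% ± 0.211, and 3.81% ± 3.86 of cells had no name. The spread between replicates far exceeded the counting error of 1 library, since the B-lineage-like share of replicate 1 had an exact 95% interval of 27.4% to 29.1% (2921 of 10337 cells) and that of replicate 3 one of 60.3% to 62.7% (3993 of 6495). The replicates also differ in age (8, 9 and 10 weeks), so age and library cannot be told apart in this spread. No cluster scored as a tissue macrophage. A CD8 T-like cluster was also led by Trdc, a gamma-delta T-cell receptor gene, so that class holds more than CD8 T cells by its transcripts.

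**Figure D1:**
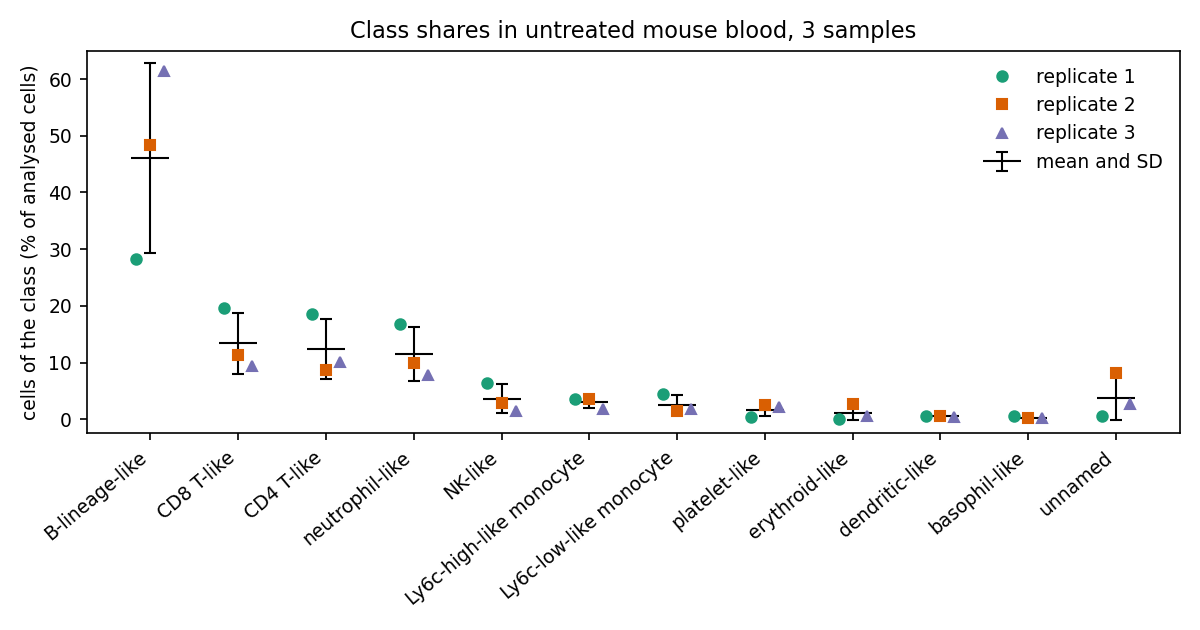
Share of analysed cells (%) in each named class and in unnamed clusters, for replicates 1 to 3 (points) with the mean and SD (bars, n = 3). B-lineage-like cells lie between 28.3% and 61.5%, and each monocyte class lies under 5%.

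Siglec1 (ENSMUSG00000027322, chromosome 2, 131069220 to 131086765, minus strand, GRCm38) was detected almost wholly in Ly6c-high-like monocytes, the classical, inflammatory monocytes of mouse blood. These held 157 of the 176 cells with a Siglec1 UMI (89.2%) and 318 of its 344 UMIs (92.4%). A Siglec1 UMI was found in 24.4% ± 1.91 of Ly6c-high-like cells (n = 3), at 59.9 ± 16.3 plain CPM. In Ly6c-low-like monocytes, the patrolling monocytes, the share was 0.949% ± 0.825, at 2.47 ± 2.34 plain CPM, and in neutrophil-like cells it was 0.230% ± 0.0504. Dendritic-like cells had the second highest share, 4.23% ± 4.35 at 9.78 ± 12.2 plain CPM, from 3 of 112 cells. B-lineage-like cells, antibody-producing lymphocytes taken as the background, held none: 0 of 9300 cells, which allows a share of cells with a UMI of up to 0.0323%. The classes differed in depth: the median UMI count was 8219 to 9308.5 in Ly6c-high-like cells, 4311 to 4860.5 in Ly6c-low-like cells and 3068 to 3224 in B-lineage-like cells. With each cell thinned to 2000 UMIs, the shares were 8.11% ± 1.53 in Ly6c-high-like, 0.298% ± 0.517 in Ly6c-low-like and 0.258% ± 0.0448 in neutrophil-like cells, and no dendritic-like cell held one.

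Against single classes, Siglec1 was higher in monocyte-like cells than in neutrophil-like cells by a log2 fold of 4.13 (SE 0.43, edgeR adjusted p = 4.89e-11) and than in dendritic-like cells by 3.08 (SE 0.62, adjusted p = 0.000153). Neutrophil-like cells held 9 Siglec1 UMIs and dendritic-like cells 4. The pooled TMM-scaled ratio was 17.3 to neutrophil-like cells (exact 95% interval 9.00 to 38.1) and 8.70 to dendritic-like cells (3.37 to 32.1). The ratio to neutrophil-like cells depends on the scaling: pooled plain CPM was 36.3 against 1.15. Over the alternatives that log2 fold ran from 3.92 to 4.95. CD8 T-like cells held 1 UMI, a ratio of 650 with an interval of 116 to 25756. Against classes with no UMI, monocyte-like cells were at least 456-fold higher than B-lineage-like, at least 173-fold higher than CD4 T-like and at least 47.5-fold higher than NK-like cells. The floor left little room in the rarer classes: at least 2.72-fold for platelet-like cells and, on plain CPM since these are outside the shared fit, 6.27-fold for erythroid-like and 3.22-fold for basophil-like cells. The planned contrast with the mean of the 7 other classes gave an adjusted p of 1.73e-21, and its fitted fold is not given because several of those classes had no UMI. With the DESeq2 Wald test the neutrophil contrast missed the threshold (log2 4.42, adjusted p = 0.0897).

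Timd4 (ENSMUSG00000055546, chromosome 11, 46810800 to 46844332, plus strand) gave 2 UMIs in 21767 cells, 1 in an NK-like and 1 in a CD4 T-like cell. None of the 1318 monocyte-like cells held one, which allows a share of cells with a UMI of up to 0.228%. Timd4 was thus not detected at this depth and with these probes in circulating monocyte-like cells, and Siglec1 and Timd4 were not found in the same cell. No class served as a positive control for Timd4, so a weak probe cannot be told from an absent transcript. The planned tests of Timd4 between classes and between positive and negative cells, and the co-detection ratio, had too few UMIs to give a value.

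**Figure D2:**
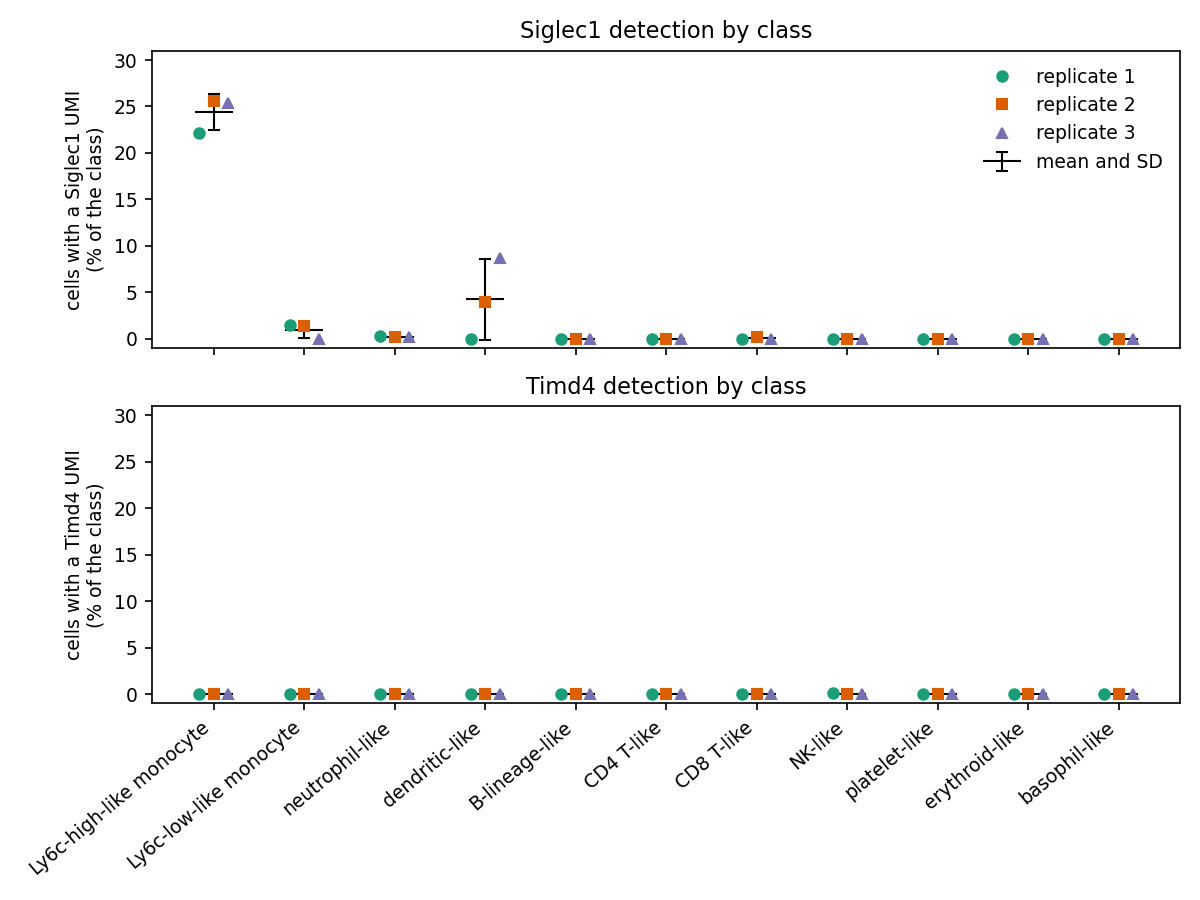
Percent of cells of each class with at least 1 UMI of Siglec1 (top) or Timd4 (bottom), for replicates 1 to 3 (points) with the mean and SD (bars, n = 3). Siglec1 stands at 24.4% in Ly6c-high-like monocytes and under 5% on average elsewhere, and Timd4 is at or near 0 in every class.

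Monocyte-like cells differed from neutrophil-like cells, the other main circulating phagocytes, in most genes tested. They were far higher in Lrp1, a receptor for apoptotic cells and lipoproteins, at 1256 ± 36.2 against 2.38 ± 1.30 TMM-scaled CPM (log2 8.74, SE 0.23), and in Fcgr1, a high-affinity Fc receptor, at 160 ± 64.8 against 0.901 ± 0.796. Ctss, a protease of antigen presentation, stood at 3759 ± 31 against 255 ± 20.9. Neutrophil-like cells were far higher in Slc40a1, the iron exporter ferroportin, at 2121 ± 286 against 2.96 ± 2.57, and in Il1b, an inflammatory cytokine, at 7001 ± 1350 against 77.8 ± 37.4. Of 10627 genes tested, 4063 were higher and 3613 lower in monocyte-like cells, and among the 8939 not used for clustering the counts were 3698 and 2862.

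The lists split in both directions between these phagocytes. Among 9 tested splenic macrophage genes 5 rose and 2 fell in monocyte-like cells. Nr1h3, the oxysterol receptor LXR alpha, rose (log2 4.23, SE 0.56, 17.0 ± 6.38 against 1.29 ± 1.02 TMM-scaled CPM), and Mrc1, the mannose receptor, rose with a pooled ratio of 88.6 (exact 95% interval 15.7 to 3519, 1 UMI in neutrophil-like cells). Siglec1 is also in this list, and Slc40a1 is the lower member with the greatest change. Of 21 efferocytosis genes 10 rose and 8 fell, with Axl, a receptor tyrosine kinase for apoptotic cells, among the higher (51.5 ± 9.86 TMM-scaled CPM, 1 UMI in neutrophil-like cells, pooled ratio 219 with an exact 95% interval of 39.2 to 8677) and Cd300lf (log2 -5.12, SE 0.13) and Anxa1 (log2 -2.38, SE 0.10) among the lower. Of 19 LXR and lipid genes 10 rose and 5 fell, with Pparg, a lipid-sensing nuclear receptor, and Lpl, lipoprotein lipase, higher, and the LXR targets Mylip (log2 -2.27, SE 0.13) and Abcg1 (log2 -1.34, SE 0.12) lower. Of 13 MHC class II presentation genes 5 rose, among them Ctss and H2-DMa (log2 3.85, SE 0.38), and 2 fell, among them the costimulator Cd80 (log2 -2.73, SE 0.15). Adjusted over the list alone, the higher count was 4 for MHC class II presentation and the lower count 12 for adhesion, and those of the other 9 outcome lists were as over all genes.

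Interferon-stimulated genes also went both ways, with 8 of 25 higher, such as Zbp1 (log2 2.60, SE 0.16) and Xaf1 (log2 2.17, SE 0.18), and 14 lower, such as Ddx60 (log2 -3.66, SE 0.17) and Oasl1 (log2 -3.14, SE 0.18). Of 22 adhesion and trafficking genes 7 rose, with S1pr5, a receptor for sphingosine-1-phosphate, at log2 7.55 (SE 0.35), and 11 fell, with the chemokine receptor Ccr1 at log2 -5.79 (SE 0.13). Of 19 tissue repair genes 7 rose, with the growth factor Pdgfb among them, and 11 fell, with the interleukin-1 antagonist Il1rn at log2 -5.79 (SE 0.13) and Vegfa at least 117-fold lower. Cxcr3, a chemokine receptor of lymphocytes, fell (log2 -3.49) and without replicate 1 did not pass (-2.91, adjusted p = 0.0588). Of 14 inflammatory genes 3 rose and 9 fell, and of 19 phagocytic receptor and lysosome genes 10 rose, such as the scavenger receptor Msr1, and 7 fell, such as the complement receptor C5ar1 (log2 -5.10, SE 0.12). Of 8 proliferation genes 2 rose, Mcm5 and Pcna, and none fell. The immediate-early and heat shock list was the only outcome list called by camera, with 9 of 12 genes lower in monocyte-like cells, such as Dusp1 (log2 -5.07, SE 0.16), and 1 higher (adjusted p = 0.0296). With an estimated correlation its adjusted p = 0.494.

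Outside the lists and the clustering genes, Mcub, a subunit of the mitochondrial calcium channel, was at least 202-fold higher in monocyte-like cells (141 ± 23.8 TMM-scaled CPM, 0 UMIs in neutrophil-like cells), and 7 further genes, Plcb1, Cyp2ab1, Tbc1d9, Lrrc8b, Abca6, Itga1 and Sestd1, were also without a UMI in neutrophil-like cells. Sycp2 was at least 331-fold lower, and Ifnlr1, the interferon lambda receptor, had 1 UMI in monocyte-like and 259 in neutrophil-like cells. Red cell transcripts moved with this comparison: 7 of 7 erythroid markers were lower in monocyte-like cells (median log2 -2.74), as were 3 of 8 platelet markers and 3 of 10 T-cell markers, while none of 8 B-cell markers passed. Of 6 conventional dendritic markers 4 were higher and 1 lower, of 3 eosinophil markers 2 were lower, and of 8 NK markers 3 were lower and 1 higher. In replicates 2 and 3 the median neutrophil-like cell held 15 and 2 haemoglobin UMIs, at a lower UMI total per cell. The median Ly6c-high-like cell held 19 and 5, and the median Ly6c-low-like cell 21 and 2. The 5% of neutrophil-like cells with the most held 59.6% and 87.6% of their haemoglobin UMIs. Scaling mattered here, since the median log2 of all genes was 0.07 with TMM, 0.29 with DESeq2 size factors and 0.92 with plain library totals, under which 6677 genes were higher and 1690 lower (79.8% higher, against 52.9%). On plain totals the medians of the interferon list (-0.54 to 0.27) and of the adhesion list (-0.68 to 0.16) turned positive, and the medians of the other 9 outcome lists kept their sign.

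Within the monocyte-like cells, the Ly6c-low-like class was higher in Cd36, Pparg, Fcgr4 and Itgax and lower in most genes of the interferon-stimulated and MHC class II presentation lists. Cd36, a scavenger receptor for oxidised lipids and apoptotic cells, stood at 801 ± 77.4 in Ly6c-low-like against 26.4 ± 8.21 TMM-scaled CPM in Ly6c-high-like cells (log2 5.02, SE 0.12), and Pparg at 170 ± 44.8 against 9.32 ± 0.466. Fcgr4, an activating Fc receptor, rose to 1005 ± 221 from 30.02 ± 13.5, and Itgax, the integrin CD11c, to 345 ± 17.9 from 8.67 ± 5.61. Other Fc receptor genes, chosen after their values were seen, mostly went the other way: Fcgr1 fell to 71.5 ± 20.3 from 202 ± 63.1 (log2 -1.47, SE 0.12), Fcgr2b to 162 ± 44.6 from 374 ± 17.0 (log2 -1.17, SE 0.11) and Fcgr3 to 279 ± 38.6 from 547 ± 70.8 (log2 -0.90, SE 0.09), while Fcer1g rose (log2 0.45, SE 0.06). Siglec1 fell by 3.83 on the log2 scale (SE 0.33) to 2.48 ± 2.34 from 59.6 ± 16.1. Of 8480 genes tested, 1595 were higher and 1823 lower in Ly6c-low-like cells, and among the 7506 not used for clustering the counts were 1325 and 1446.

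**Figure D3:**
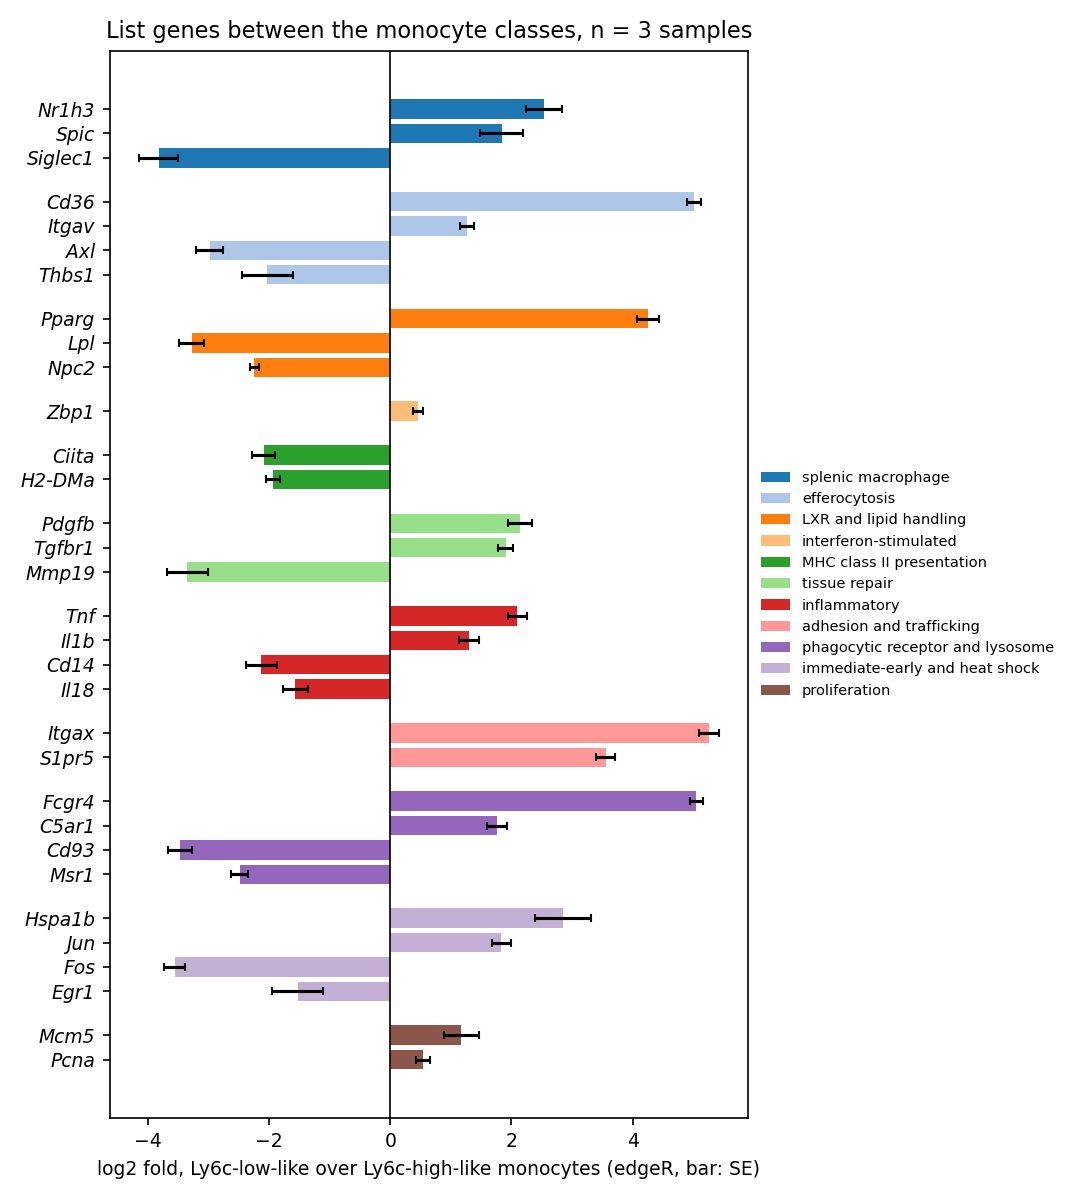
Log2 fold with its SE (edgeR, n = 3 samples) of Ly6c-low-like over Ly6c-high-like monocytes for named list genes with more than 3 UMIs in each class, coloured by list (a gene in 2 lists is drawn once). Itgax, Fcgr4 and Cd36 lie above 5, and Siglec1 and Fos lie below -3.5.

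Nr1h3 (ENSMUSG00000002108, chromosome 2, 91184061 to 91202834, minus strand) rose in Ly6c-low-like cells (log2 2.54, SE 0.29, 37.6 ± 14 against 7.03 ± 1.36 TMM-scaled CPM), as did Spic, a transcription factor of red pulp macrophages (log2 1.84, SE 0.35). Of the 6 tested splenic macrophage genes these and Adgre1 rose, Mrc1 and Siglec1 fell, and Hmox1 did not pass (380 ± 180 against 196 ± 32.5). The median log2 of this list was 0.63 and its mean -0.75. Of 19 LXR and lipid genes 11 rose, among them Apoe, a lipoprotein component (5734 ± 1239 against 2746 ± 333), and 5 fell, among them Lpl (log2 -3.28, SE 0.20) and the lysosomal cholesterol carrier Npc2 (log2 -2.25, SE 0.07). Adjusted over the list alone 13 rose. Of 18 efferocytosis genes 7 rose, with Cd36 and the integrin Itgav (log2 1.27, SE 0.11), and 6 fell, with Axl at 7.90 ± 2.29 against 72.9 ± 5.92. Thbs1, an adhesive glycoprotein of platelets, also fell (log2 -2.03, SE 0.42), and without replicate 1 it did not pass (-0.99, adjusted p = 0.169).

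Interferon-stimulated genes were lower in Ly6c-low-like cells in 22 of 25 tested members (23 adjusted over the list alone), with a median log2 of -1.40. Isg15, a ubiquitin-like interferon effector, stood at 17.4 ± 4.37 against 128 ± 22.3 TMM-scaled CPM, and Irf7, a regulator of interferon genes, at 194 ± 18 against 431 ± 65.5. Ifit1 (3 UMIs in Ly6c-low-like cells) had a pooled ratio of 22.6 in favour of Ly6c-high-like cells (exact 95% interval 7.56 to 111), and Zbp1 was the 1 member that rose (log2 0.46, SE 0.09). Camera called the list at an adjusted p = 3.48e-12, and with an estimated correlation the adjusted p = 0.517. MHC class II presentation genes fell in 9 of 13 (10 adjusted over the list alone), with the class II transactivator Ciita at log2 -2.09 (SE 0.19) and H2-DMa at -1.94 (SE 0.11), at an adjusted p = 0.00163 and, with an estimated correlation, an adjusted p = 0.517. The adhesion and trafficking list was called higher at an adjusted p = 0.00163, with 12 of 21 members higher, such as S1pr5 (log2 3.56, SE 0.15), and 5 lower, such as Ccr1 (6 lower adjusted over the list alone). With an estimated correlation its adjusted p = 0.517.

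The other lists were mixed. Of 14 tissue repair genes 5 rose, such as Pdgfb (log2 2.14, SE 0.20) and the TGF-beta receptor Tgfbr1 (log2 1.91, SE 0.12), and 8 fell, such as the metalloprotease Mmp19 (log2 -3.35, SE 0.34). Of 11 inflammatory genes 4 rose, with Tnf at 111 ± 18.5 against 25.6 ± 5.82 and Il1b at log2 1.30, and 4 fell (5 adjusted over the list alone), with Cd14, a receptor for bacterial lipopolysaccharide, at 10.8 ± 5.47 against 44.5 ± 9.38. Of 19 phagocytic receptor and lysosome genes 7 rose and 8 fell, the latter with Cd93 (log2 -3.47, SE 0.20) and Msr1 (log2 -2.48, SE 0.14). Of 12 immediate-early and heat shock genes 5 rose, with Hspa1b and Jun (log2 1.84, SE 0.15), and 3 fell, with Fos at 16.0 ± 11.2 against 246 ± 66.6. Il1b did not pass with doublets kept (log2 0.97, adjusted p = 0.322) or with no replicate block (adjusted p = 0.101). The 2 tested proliferation genes, Mcm5 and Pcna, rose, and Mcm5 did not pass without replicate 1 (log2 1.03, adjusted p = 0.0861) or with the DESeq2 Wald test (log2 1.15, adjusted p = 0.0859). Egr1 fell (log2 -1.53) and did not pass without replicate 1 (-0.70, adjusted p = 0.429) or with the Wald test (-1.32, adjusted p = 0.206). Outside the lists and the clustering genes, the beta-adrenergic receptor Adrb1 was higher with a pooled ratio of 183 (exact 95% interval 50 to 1520, 2 UMIs in Ly6c-high-like cells) and the connexin Gjb2 at log2 5.73 (SE 0.41), while Mfsd7a (log2 -5.00, SE 0.27) and Ms4a8a (log2 -4.70, SE 0.26) were lower.

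Markers of other cell types also differed between the monocyte classes. All 4 tested markers of conventional dendritic cells were lower in Ly6c-low-like cells, with Cd209a at 0.141 ± 0.245 against 68.9 ± 24.1 TMM-scaled CPM, and 3 of 4 neutrophil markers were lower. Of 4 erythroid markers 1 was higher, Hba-a2 (log2 0.93, SE 0.20), and the median of the 4 was 1.02. Of 7 B-cell markers 1 passed as higher, and of 5 T-cell markers none did. The number of changed genes fell to 1707 with the DESeq2 Wald test and to 2102 without replicate 1, which holds 374 of the 664 Ly6c-high-like and 468 of the 654 Ly6c-low-like cells.

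Monocyte-like cells with a Siglec1 UMI carried more interferon-stimulated transcripts than matched cells without one. Rtp4, a chaperone induced by interferon, stood at 224 ± 24.0 against 69.9 ± 19.9 TMM-scaled CPM (log2 1.67, SE 0.14, adjusted p = 8.07e-08). Irf7 stood at 771 ± 216 against 314 ± 42.1 (log2 1.25, SE 0.14), Oasl2, of the oligoadenylate synthetase family, at 415 ± 52.1 against 148 ± 43.1 (log2 1.42, SE 0.18), and Isg15 at 241 ± 57.3 against 87.4 ± 31.3 (log2 1.39, SE 0.21), each higher in 3 of 3 samples. The interferon-stimulated list as a whole took 7429 ± 930 plain CPM in positive and 3999 ± 878 in negative cells, with log2 ratios of 0.96, 0.45 and 1.32 in replicates 1, 2 and 3. The arms held 90, 44 and 30 positive and 270, 131 and 88 negative cells. Of the positive cells 83, 43 and 30 were Ly6c-high-like and 7, 1 and 0 Ly6c-low-like, so the result says little about Ly6c-low-like cells. With Ly6c-high-like cells only, 90 genes changed, 89 of them shared with the main fit. Median depths were 8923, 9480.5 and 8745.5 UMIs against 8865.5, 8947 and 8123.5. In replicates 2 and 3 all 128 and 88 Siglec1-negative Ly6c-high-like cells were used. Matching there held the class equal but chose none of these cells by depth, and positive cells stayed deeper. In replicate 2, 44 of 45 positive cells found a match.

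Of 7790 genes tested, 88 were higher and 5 lower in positive cells, and among the 6909 not used for clustering the counts were 55 and 1. Of the 25 tested interferon-stimulated genes 11 were higher (22 adjusted over the list alone) and none was lower, with a median log2 of 1.21. Among them are Sp100, Isg15, Oasl2, Oasl1, Oas2, Oas1a, Irf7, Xaf1, Rtp4 and Parp14. Camera called the list at an adjusted p = 2.88e-94. With an estimated correlation its unadjusted p = 0.0220 and its adjusted p = 0.220. Several strongly inducible members did not pass and varied between replicates: Ifit3 took 215 against 37.1 plain CPM in replicate 1, 76.5 against 92.9 in replicate 2 and 315 against 20.1 in replicate 3, and Rsad2, an antiviral enzyme, took 60.3 against 71.6 in replicate 2. Outside the list, the helicase Mov10 (log2 1.54, SE 0.32), the complement factor Cfb (log2 1.5, SE 0.30) and the guanylate-binding protein Gbp5 (log2 1.34, SE 0.25) were higher, and B4galnt1, a ganglioside synthase, was lower (log2 -0.46, SE 0.11).

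**Figure D4:**
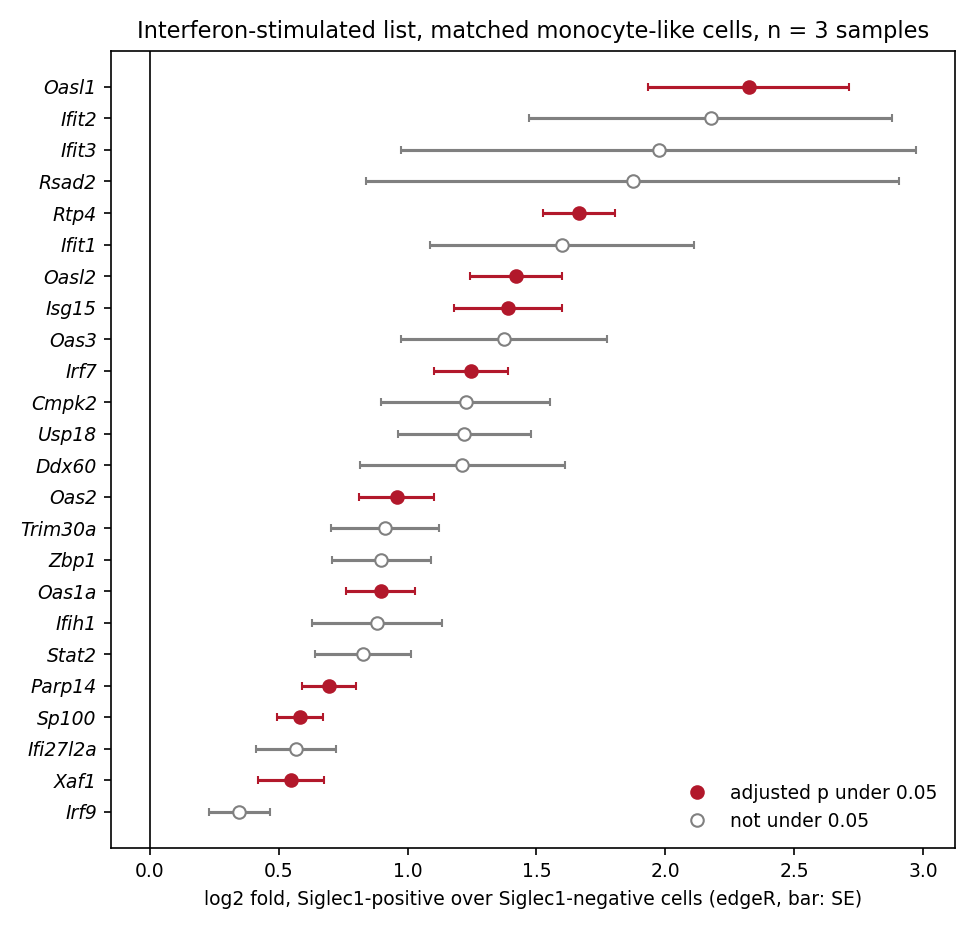
Log2 fold with its SE (edgeR, n = 3 samples) of Siglec1-positive over matched Siglec1-negative monocyte-like cells for tested interferon-stimulated genes, filled where the adjusted p over all genes was under 0.05. All genes drawn lie above 0, with Oasl1 highest at 2.32.

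No gene of the other 10 outcome lists passed over all genes. Adjusted over the list alone, 3 of 19 phagocytic receptor and lysosome genes, 2 of 11 inflammatory genes and 1 each of the efferocytosis, LXR and lipid, MHC class II presentation, and immediate-early lists were higher, and 1 each of the splenic macrophage and tissue repair lists was lower. Camera called the phagocytic list (adjusted p = 0.0117) and the inflammatory list (adjusted p = 0.0390) higher and the 3 tested splenic macrophage genes lower (adjusted p = 0.0117). With an estimated correlation each of these had an adjusted p = 0.390. Mrc1 had 13.6 ± 7.60 against 39.4 ± 7.18 TMM-scaled CPM (adjusted p = 0.107).

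Markers of other cells moved with the Siglec1 arms. Of 4 tested erythroid markers 2 were lower in positive cells, Alas2 (log2 -1.38, SE 0.27) and Hbb-bt (log2 -1.01, SE 0.14). The 4 T-cell and the 4 neutrophil markers tested had medians of 1.04 and 1.07 and none passed. Cells with 2 or more lymphocyte marker UMIs made up 20%, 27.3% and 33.3% of positive and 12.96%, 10.7% and 35.2% of negative cells, and without such cells 19 interferon-stimulated genes were higher. The number of changed genes rested on single replicates: it was 16 without replicate 3, of which 14 were among the 93, 76 without replicate 1 (48 shared) and 159 without replicate 2 (82 shared). Without replicate 3 the interferon-stimulated genes higher were 5, with Rtp4 at an adjusted p = 0.0133, Oasl2 at 0.0133, Irf7 at 0.0161 and Isg15 at 0.0458, while Oasl1 (0.260), Gbp5 (0.231), Cfb (0.307), Mov10 (0.451) and B4galnt1 (0.300) did not pass. Without replicate 1, Cfb (adjusted p = 0.166), Mov10 (0.16) and B4galnt1 (0.626) did not pass, and the interferon-stimulated genes higher were 16. With at least 2 Siglec1 UMIs per positive cell 62 genes changed, 49 of them among the 93, and 13 of 22 tested interferon-stimulated genes were higher. Rtp4 (adjusted p = 1.08e-06), Irf7 (2.04e-06) and Oasl2 (0.0114) then passed, while Isg15 (0.213), Mov10 (0.0649), Cfb (0.0561), Gbp5 (0.0556) and B4galnt1 (0.122) did not, and with unmatched arms Isg15 did not pass either (0.0502). B4galnt1 also did not pass with the Wald test (adjusted p = 1), with no replicate block (0.0707), with doublets kept (0.143) or without cells with lymphocyte markers (0.0695), nor did Cfb with no replicate block (0.0550).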

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

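The test for red cells joined with leukocytes and the test for free haemoglobin RNA were both set before their results were seen. Barcodes with fewer than 200 genes, which no comparison uses, held mostly red cell RNA: haemoglobin made up 70.4%, 79.7% and 76.7% of their UMIs in replicates 1, 2 and 3, with 101, 685 and 396 such barcodes. An unnamed cluster with the transcripts of both red cells and B cells, also in no comparison, held 0.242%, 7.19% and 1.91% of cells.

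In the cells that were kept, haemoglobin took 0.0793%, 3.02% and 0.665% of UMIs, and in replicates 2 and 3 it reached every tested leukocyte class. The test for free haemoglobin RNA in all droplets took 90% or more of the cells of each class with a UMI as for it and under 50% in some class as against it, and the shares of 7 classes in those replicates ran from 83.5% to 100%, which meets neither. Red cells joined with a few leukocytes predict that few cells hold most of it, and the 5% of cells with the most held a median of 48.7% over the classes, from 15.5% to 87.6%. Over both replicates neither test met its bound in every class. In replicate 2 every class met the bound for free RNA (99.96% to 100% of cells), and in replicate 3 only neutrophil-like cells (83.5%) missed it. A low level in nearly all cells and a few cells with much more are both present. How much each explanation contributes cannot be told for these 7 classes, and no empty droplets are in the matrices. The unnamed cluster with red cell and B-cell transcripts lies outside the 7 classes, so its cells did not enter the test for joined cells. The design gives no group that differs in red cells, so no biological explanation was tested.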

How the results depend on the processing

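Plain library totals, the removal of cells with lymphocyte markers and the restriction to Ly6c-high-like cells were chosen after seeing the data. Siglec1 in monocyte-like cells against the mean of the other classes kept its direction and passed under all 9 alternatives. Of 44 values of the shares of 12 classes and of unnamed cells under other processing, 42 moved by less than 1 SD between replicates. With a minimum of 500 genes the platelet-like share fell from 1.69% to 0.692%, still by less than 1 SD. Leaving out a replicate cannot move a mean of 3 by 1 SD, so it is no test of these shares: without replicate 2 the erythroid-like share fell from 1.11% to 0.358% and the unnamed share from 3.81% to 1.67%. With a replicate left out the Ly6c-low-like share fell as low as 1.61% from 2.58%, the NK-like share 2.21% from 3.61% and the basophil-like share 0.189% from 0.310%. At resolution 0.5 the monocyte-like share fell from 5.56% to 2.53%, as a cluster of 790 cells with Ly6c-high-like and dendritic markers was left unnamed. The unnamed share rose from 3.81% to 8.83%, since a cluster of 435 cells with platelet and erythroid markers was also left unnamed. Between monocyte-like and neutrophil-like cells the count of changed genes stayed within 1.5 times 7676 in every setting, while plain totals moved its split as given above. Between the monocyte classes the count of 3418 fell to 1707 with the DESeq2 Wald test, and with a replicate left out it ran from 2102 (without replicate 1) to 3310 (without replicate 2). Between the Siglec1 arms the count of 93 was 37 with the Wald test, 141 with no filter and 54 with no replicate block. With unmatched arms, which differ in depth and class, it was 506. These were 248 higher and 258 lower, so the mostly one-sided split of the matched arms was lost. With a replicate left out the count ran from 16 (without replicate 3) to 159 (without replicate 2). The cause was not tested for these changes. Of the 93 genes, 27 were shared with the Wald test, 50 with the fit without a block and 84 with the unmatched arms. Of the named genes, 472 of 479 alternative values kept their call between the monocyte classes, 527 of 530 against neutrophil-like cells and 93 of 112 between the Siglec1 arms, and no value reversed. Genes without a value in a setting were left out of these counts. Of the 9 named genes of the Siglec1 arms, 4 kept their call with the Wald test, 1 lost it and the rest had no value. Lists called fell to 0 in each comparison with an estimated correlation. The fry test gave other calls. Against neutrophil-like cells it called every outcome list (adjusted p of 0.0102 or less), with splenic macrophage lower, where camera had it higher and uncalled. Between the monocyte classes it called the adhesion and inflammatory lists higher (adjusted p = 0.0291 each) and not the interferon list (0.0791). Between the Siglec1 arms it called none (interferon list, adjusted p = 0.173). Timd4 had too few UMIs for a value: its planned tests and the co-detection ratio have none under any alternative, its adjusted p with no filter was 1, and with doublets kept it had 2 UMIs, 0 of them in 1456 monocyte-like cells. Classes without a value are the Ly6c-high-like, dendritic-like, platelet-like and erythroid-like ones at resolution 0.5, the erythroid-like one at resolution 2 and with a minimum of 500 genes, and the erythroid-like and platelet-like ones with doublets kept. At these library sizes, with 3 samples and the assumed spread, 18.2% of simulated 1.5-fold changes were recovered between the Siglec1 arms, against 69.4% of 2-fold ones.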

Other observations

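Of the tests reported in this part, those for control genes and for granule transcripts held by a few cells were set before their results, and the others were chosen after the results were seen. Some genes of the splenic macrophage list, chosen here after their values were seen, were found in other classes than the monocyte-like ones. Mrc1 was highest in dendritic-like cells (87.8 ± 19.6 plain CPM, against 33.2 ± 3.15 in Ly6c-high-like cells), as was Cd163, a haemoglobin scavenger receptor (31.9 ± 24.7). Itgad, an integrin of red pulp macrophages, was found mainly in NK-like cells (35.8 ± 22.4), Slc40a1 in neutrophil-like cells (1238 ± 77) and Spic in Ly6c-low-like (23.7 ± 3.42) and B-lineage-like cells (10.2 ± 2.81). Vcam1 had no UMI in either monocyte class.

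A B-lineage-like cluster led by interferon-stimulated genes, such as Ifit3, Oasl1, Irf7 and Usp18, held 136 cells, or 1.51% ± 0.295 of B-lineage-like cells. The interferon-stimulated list took 9605 ± 176 plain CPM there, against 2010 ± 154 in all B-lineage-like, 4906 ± 564 in Ly6c-high-like and 2424 ± 577 in Ly6c-low-like cells. This cluster was picked for its interferon-stimulated genes, so its high level follows from that choice and is no test. Its top 10 genes also include Slfn5, Ifit3b and Irgm1, which are outside the list and were not held out of the clustering. No Siglec1 UMI was found in any B-lineage-like cell, so in these samples the interferon genes were seen without Siglec1 in that lineage.

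The higher interferon-stimulated genes in Siglec1-positive monocyte-like cells could come from depth, and 0 of 100 control genes of a similar UMI total split Ly6c-high-like cells as far as Siglec1 did (mean log2 ratio 0.90, highest control 0.47), which argues against it. RNA of other blood cells would need cells richer in these genes. Outside erythroid-like cells the highest ratio of a whole class to the positive cells was 0.619 (neutrophil-like, replicate 2). That argues against RNA of a whole class at its mean level. A class mean cannot exclude a richer subset, and a subset was checked by its own markers only for B-lineage-like cells. Of RNA from the richer interferon-led B-lineage-like cluster, the B-cell markers in positive cells allow at most 7.40% of what the rise needs. That argues against RNA of this cluster. Red cell RNA would raise erythroid markers, and their median log2 was -1.06, while without cells that carry lymphocyte markers 19 interferon-stimulated genes were higher, which argues against joined lymphocytes. Tissue macrophage markers reached 11.9 CPM in the positive cells, past the bound of 10 set for some macrophages among them, yet 16 of the 18 UMIs sat in 1 cell, at most 3.33% of positive cells of a sample held any, and without the cells that held one at least 96.5% of the log2 ratio remained in each sample, which argues against macrophages as most of the positive cells and against those cells as carriers of the rise. A link of Siglec1 with an interferon state of Ly6c-high-like monocytes is a hypothesis found and tested on the same data, and the design has no group that differs in interferon. The arms were chosen by Siglec1 itself, so the values show co-expression. They cannot tell whether Siglec1 is itself 1 of the interferon-stimulated genes, in which case the rise would follow from the choice of cells.

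Regrouping the 6 sums of each comparison gives only 10 splits, so no share can fall under 0.05. The real split was the 1 with as many genes in each comparison: 93 between the Siglec1 arms (highest other 3), 6621 between monocyte-like and neutrophil-like cells in the fit of these 2 classes (highest other 0) and 3418 between the monocyte classes (highest other 0). The classes were made by clustering these same cells, so the real split between classes was bound to lead. No conclusion on chance is drawn from these counts.

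Granule genes of immature neutrophils (Camp, Ltf and Ngp together) took 1657 plain CPM in the neutrophil-like cells of replicate 2, against 89.3 and 28.5 in replicates 1 and 3. Free granule RNA would reach other classes, and the highest of these stood at 2.99% of the neutrophil-like level, which argues against it. The 5% of neutrophil-like cells with the most held 98.7% of the 2322 UMIs in replicate 2. They also held 90.1% and 78.0% in replicates 1 and 3, so this share is not particular to replicate 2. In replicate 2, 5 cells held 96.4% of the UMIs, so a few cells carried most of its level. Which cells they are was not tested, and no biological explanation was tested.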
